A study of Solanum lycopersicum with 12 samples.

How the data were processed

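Pericarp RNA of tomato fruit carrying the hp-2dg mutation was set against pericarp RNA of its wild-type counterpart on the TOM1 cDNA microarray, a 2-colour spotted array, at the mature green, breaker and red stages. Each stage had 4 arrays. In 3 of them, per the labels, separate harvests served as biological repeats, with the mutant in Cy5 and the wild type in Cy3. The remaining array was a technical repeat with the dyes exchanged, called the swapped array here and the forward arrays being the other 9. Each harvest pooled fruit of several plants, so the spread between repeats is that between pools. Replicates 1 to 3 were numbered in accession order.

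Per the labels, RNA was amplified before labelling, slides were scanned on a ScanArray 4000, and spots were quantified in QuantArray version 3. Spot intensity and local background intensity are on a linear scale, not normalized, per the file headers. The scanner's signal to noise score divides a spot's intensity by the spread of its background, which was found by setting the deposited columns against each other. The authors' value table holds log2 ratios of mutant over wild type, made per the labels in Genespring 7.2 with a Lowess curve and a floor on the control channel. Its columns correlated with the background-subtracted scanner ratios at Pearson's r of 0.836 to 0.998 across spots, which settles direction. Pearson's r does not test the base of the logarithm. Its column medians ran from -0.12 to 0.01, so its centring is not that of the values used here. All of its columns were mapped to an array.

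Intensities were background corrected by normexp with an offset of 50 and normalized within each array by loess with a span of 0.4, in limma 3.58.1 under R 4.3.3. On every file, channel 1 holds the wild type, so each ratio is mutant over wild type on forward and swapped arrays alike. Spots were kept where the signal to noise ratio was at least 2 in either channel on at least 3 of the 4 arrays of at least 1 stage, which left 12826 of 13440 spots. A dye effect was estimated for each spot from the difference between forward and swapped arrays, averaged over the 3 stages, and removed. Its SD across spots was 0.137. Across spots, the dye estimates of mature green and breaker correlated at 0.232. Those of red correlated at 0.0012 with mature green and at -0.0054 with breaker. The forward red arrays appear to differ from the swapped red array in print layout. Part of that difference may therefore enter the values of every stage. The 9 forward arrays entered one limma model with a mean for each stage, 6 residual degrees of freedom and 3.80 prior degrees of freedom. Two-sided moderated tests were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The swapped arrays added no replicate, since they share an extract with a forward array.

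The dye estimate is shared by the stages and its error is not in the model. It can raise the variance of a stage mean by a factor of up to 1.17 and that of the average over stages by up to 1.5. The procedure was tested on simulated data with the measured spreads of 12826 spots, 200 of them changed. At mature green it recovered 34.3% of the changes of 1.5-fold, 79.1% of those of 2-fold and 97.0% of those of 3-fold, and 10.3% of its calls were false. For the average the values were 80.6%, 97.0% and 100%, and 15.1% of calls were false. With no change simulated, 5.80% of spots had an unadjusted p under 0.05 at mature green and 8.01% did for the average, so the average test is too liberal. The simulation gave each spot the same dye effect at all stages. The measured red dye estimates did not correlate with the others, so these rates are approximate. The data also gave far more calls than the 200 changed spots, 2522 at mature green and 3715 for the average. The Benjamini-Hochberg cutoff depends on that number, so the recovery rates and shares of false calls do not carry over to the data. Widened errors gave 2219 calls at mature green, 1445 at breaker and 2049 at red. For the average, counts with widened errors stand beside the reported ones.

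The ripening change was computed from the mean log2 intensity of both channels, quantile normalized, on the forward arrays of red and mature green. Intervals on correlations come from resampling print positions 1000 times (300 times for the slower tests) and give 95% limits across spots, not across fruit.

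The files do not pair spots with genes. The 19 gene lists and the markers of other tissues fixed before the data were examined therefore gave no result, and genes chosen by name were not analysed here. The rule fixed at the same time for genes to name takes the 8 highest and 8 lowest of each comparison among spots with a gene name, so it named none. Once the files were seen to hold no gene names, it was reduced to spot numbers and to the average over stages. There, 1228 spots passed the threshold with the same sign on all 12 arrays, and the 2 highest and 2 lowest of them are named. The alternatives tried were other background, normalization and filter settings, other uses of the swapped arrays, array weights, separate fits, the scan day, the deposited value table and leaving out each array.

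The number of arrays limits the precision. Between 68.2% and 88.4% of spots in the wild-type channel, and between 74.7% and 90.8% in the mutant channel, reached the signal to noise minimum. The 12 arrays were scanned on 7 days, each day held arrays of 1 stage, and each stage spanned at least 2 days, so the scan day was tried as a random block and no day gives a comparison between stages. The headers of the breaker files name another cultivar as the wild type than the labels do, which is not settled here. If the headers are right, the breaker ratios mix cultivar with genotype. The average over stages and the comparisons with breaker would then do so too.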

Results

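The data compare fruit pericarp of the tomato mutant hp-2dg with wild-type pericarp at mature green, breaker and red. The mutation lies in DET1, a repressor of light responses, and hp-2dg fruit are known for their raised pigment content. Each stage was measured on 3 arrays of separate harvests and on 1 swapped array. Median spot intensity per array ran from 1868 to 4378 in the mutant channel and from 1557 to 4733 in the wild-type channel. All log2 ratios are mutant over wild type.

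At mature green, the question was which transcripts differ between the genotypes before ripening. The mutant was higher at 1785 spots and lower at 737, together 19.7% of the 12826 tested (limma, Benjamini-Hochberg). Large differences ran mainly toward higher signal in the mutant. Of the called spots, 1032 were at least 2-fold higher and 108 at least 2-fold lower, and 139 were at least 8-fold higher. The median called increase was 1.14 and the median called decrease -0.66 on the log2 scale, and the extremes were 6.02 and -2.81. Of all called spots, 2469 had the same sign on the 3 harvests and the swapped array. The deposited value table, whose median log2 ratio over spots at this stage was -0.11, split its calls into 1538 higher and 1561 lower, while 950 were at least 2-fold higher and 323 at least 2-fold lower. Leaving out replicate 1, 2 or 3 left 1731, 1511 and 1659 calls, with 363, 280 and 359 lower, and array weights gave 4199, of which 1645 were lower. With the scan day as a random block 1320 were lower.

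At breaker, the onset of colour change, the mutant was higher at 1258 spots and lower at 515. If the wild-type cultivar named in the headers is right, these differences mix cultivar with genotype. At least 2-fold differences again lay mainly on the higher side, with 705 spots higher and 92 lower. The extremes were 4.05 and -4.28 on the log2 scale. With the deposited value table, 1085 spots were higher and 771 lower, with 700 and 192 at 2-fold or more. Without replicate 2 there were 763 higher and 216 lower, without the swapped array 784 lower, and without replicate 3 there were 793 and 233 at 2-fold or more. Fitted on its own 3 arrays this stage gave 381 calls, with array weights 1159 and with the scan day as a random block 2939.

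In red fruit, 1453 spots were higher in the mutant and 1052 lower. At least 2-fold differences numbered 538 higher and 284 lower, with a lowest value of -4.43. The highest, 4.21 at spot 12736, includes a replicate without wild-type signal above background and was 3.20 without it. The higher side held 65.5% of these, against 90.5% at mature green and 88.5% at breaker, and 60.9%, 74.6% and 78.5% with the deposited value table. The difference between these shares was not tested. The swapped arrays were also taken alone, without dye correction. Of their spots at 2-fold or more, 71.4% were higher at red, 72.6% at breaker and 84.9% at mature green. Leaving out replicate 1, 2 or 3 left 1000, 844 and 800 higher and 572, 499 and 566 lower. With the scan day as a random block 2073 were higher and 1623 lower. The forward red arrays appear to differ from the other 9 arrays in where some products are printed. A search of the signal for shifted runs of positions found 768 spots, 5.71% of the array, whose product appears to differ between the layouts. Further positions may differ too. At only 205 of 420 print positions did the signal correlate at 0.7 or more with that of the other 9 arrays. Without the 768 spots 2385 calls were made at red.

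Averaged over stages, 2230 spots were higher and 1485 lower in the mutant, of which 699 were at least 2-fold higher and 39 at least 2-fold lower. With standard errors widened for the error of the dye estimate, 2660 spots passed, 1822 higher and 838 lower. The deposited value table gave 1877 higher and 2317 lower, with 670 and 90 at 2-fold or more. Without the swapped red array 59 were at least 2-fold lower.

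The named spots show the sizes reached. Spot 8167, in block row 5 and block column 4, had the lowest log2 ratio averaged over stages. Its log2 ratio was -1.38 ± 0.20 (SD, n = 3) at mature green, -4.28 ± 0.86 at breaker and -4.43 ± 0.06 in red fruit. The corresponding fold decreases were 2.60, 19.5 and 21.5, and the adjusted p values were 0.0033, 8e-05 and 4e-05 (limma). Its effect differed between stages (limma moderated F, adjusted p = 0.00091), and all 12 arrays gave a lower signal in the mutant. Mean wild-type intensity at this spot stayed between 34130 and 46052 and reached 55414 on breaker replicate 3, while mean mutant intensity was 11969 at mature green and 2039 in red fruit.

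Spot 9806 was lower by -1.92 ± 0.58 at mature green, -2.40 ± 0.97 at breaker and -1.69 ± 0.26 in red fruit (SD, n = 3). Fitted on the 3 breaker arrays alone, the breaker value did not pass the threshold. Wild-type intensity at breaker reached 64652 on replicate 1, near the highest recorded value of 65535, so that ratio may be compressed. On mature green replicate 1 both channels were under the signal to noise minimum. The spot lies at a print position that appears exchanged on the forward red arrays, so its red value may belong to another product than its other values. Its average over stages, by which it was named, may then mix products. Through the shared dye estimate its mature green and breaker values may be affected too. With the positions put back the red value was -2.68.

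Spot 12736 was higher by 2.26 ± 0.26 at mature green, 2.97 ± 1.01 at breaker and 4.21 ± 2.13 in red fruit (SD, n = 3). On red replicate 1, at 6.62, the wild-type channel was not above background (intensity 2250, background 3077), so that ratio is no measured fold. With values under the signal to noise minimum left out the red value was 3.20. Mean mutant intensity of this spot was 57314 at mature green and 48596 at breaker, near the highest recorded value of 65535, so those ratios may be compressed. Spot 4225 was higher by 3.87 ± 0.07, 3.39 ± 1.23 and 2.13 ± 1.49, and its red replicates ran from 0.51 to 3.44. The highest of these had a wild-type signal to noise ratio of 1.34, and with such values left out the red value was 1.29 and not called. Its mutant intensity at mature green reached 56175 on replicate 3 and 63340 on the swapped array, so these ratios may be compressed too. For neither spot did the effect differ between stages past the threshold (adjusted p = 0.29 and 0.24, limma moderated F). The call of spot 12736 at mature green was lost without replicate 1, 2 or 3, with values of 2.37, 2.15 and 2.27, and at breaker without replicate 2, with 2.48. That of spot 4225 in red fruit was lost without replicate 1 or 3, with values of 2.00 and 1.59.

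**Figure D1:**
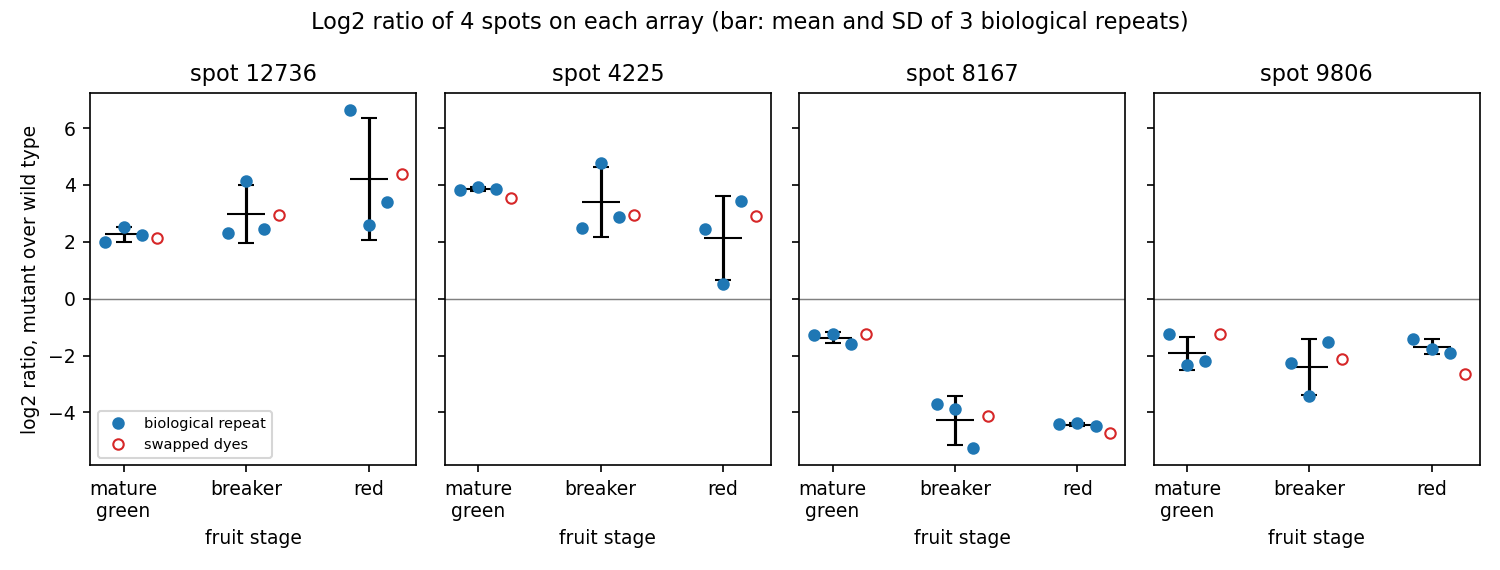
Log2 ratio of mutant over wild type (vertical axis) for 4 spots at 3 fruit stages (horizontal axis). Filled points are biological repeats, open points swapped arrays, and bars the mean and SD of the 3 repeats. The red point of spot 12736 at 6.62 has no wild-type signal above background. Spot 8167 falls from -1.38 at mature green to -4.28 at breaker and -4.43 in red fruit.

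The next question was whether the genotypes differ in the same way at each stage. Across spots, the effects at mature green and breaker correlated at r = 0.715, those at breaker and red at 0.438, and those at mature green and red at 0.321. Spots are not independent replicates. The stages share the dye estimate, so part of any excess may come from it, and unchanged spots simulated with it gave 0.102, 0.0976 and 0.0957. The covariances were 0.288, 0.140 and 0.124, against 0.00475, 0.00447 and 0.00439 in the simulation. The simulation gave each spot the same dye effect at all stages. The measured red dye estimates did not bear this out, so the simulated values are only an approximate baseline. Of the spots higher at mature green and at breaker, 1008 were shared, where independent lists of these sizes share 175. For mature green and red the shared number was 594 against 202, and for breaker and red 510 against 143. Among lower spots the shared numbers were 130 against 29.6, 90 against 60.5 and 107 against 42.2. Called in opposite directions were 12 spots for mature green and breaker, 138 for mature green and red and 51 for breaker and red. In all 3 stages, 443 spots were higher and 31 lower.

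The genotype effect differed between stages at 1872 spots (limma moderated F). These include spots whose product appears to differ between the layouts, and without the 768 spots found by the search the count was 1700. Further positions may differ too, so 1700 is not free of the layout, and the comparisons with red share this limit. Breaker and mature green differed at 258 spots, red and breaker at 1098, and red and mature green at 2012. In the last comparison the effect was lower in red fruit at 1206 spots and higher at 806. The 139 spots at least 8-fold higher at mature green, chosen by their values there, had a median log2 ratio of 3.75 there, 2.41 at breaker and 0.41 on the forward red arrays. On the swapped red array their median was 1.27. The count of 1872 fell to 991 without mature green replicate 2, 1058 without red replicate 2, 1177 without red replicate 3 and 1211 without mature green replicate 1. It was 2810 with array weights and 3734 with the scan day as a random block.

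**Figure D2:**
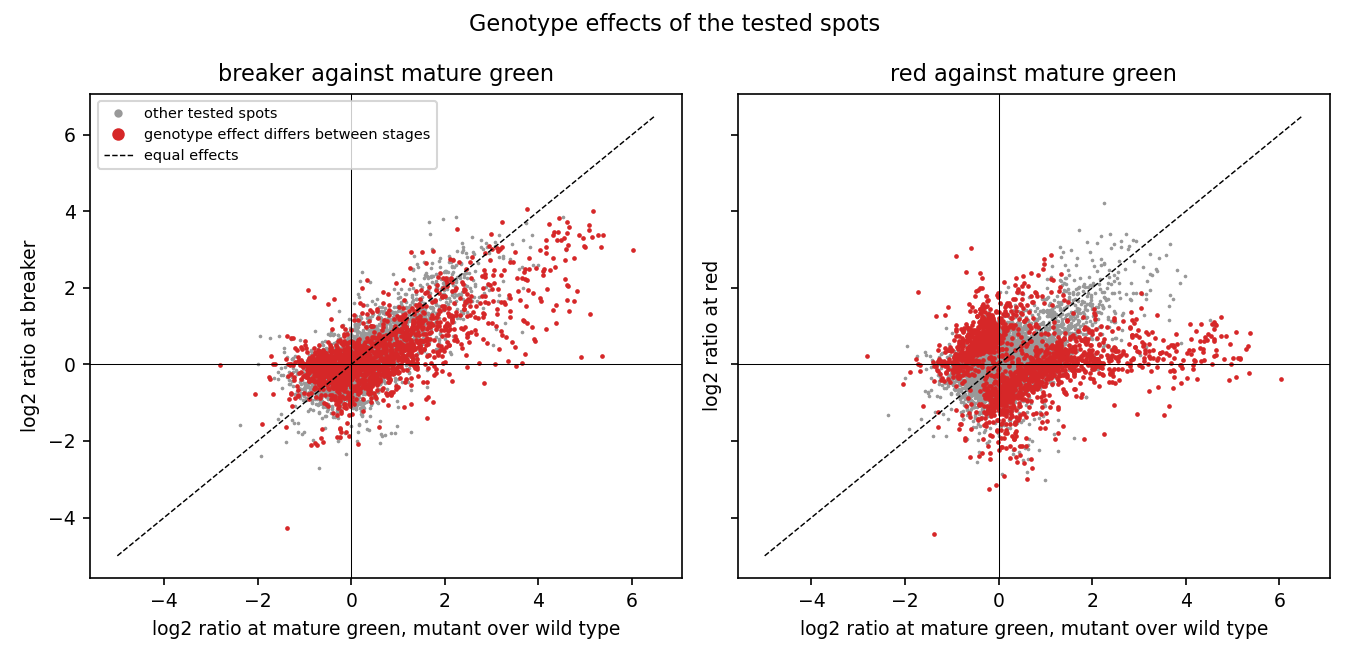
Log2 ratio of mutant over wild type at breaker (left) and red (right) against that at mature green, 1 point per tested spot. Coloured points are the 1872 spots whose effect differed between stages, and the dashed line marks equal effects. The 1032 called spots at least 2-fold higher at mature green have a median of 1.64 there, 1.17 at breaker and 0.51 at red.

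Signal of both genotypes together was compared between red and mature green. It was higher in red fruit at 3568 spots and lower at 3473. The forward red arrays appear to carry another print layout, so these counts cannot tell layout from ripening. Across spots, this change correlated at 0.468 with the change from mature green to the swapped red array. The change from mature green to breaker, whose arrays share a layout, correlated with the latter at 0.741. Each of these changes uses the mature green signal. Between breaker and mature green, 1092 spots were higher and 1276 lower. The change from mature green to red correlated with the genotype effect at breaker at r = -0.138 across spots (95% limits -0.163 to -0.110). This signal includes the mutant channel at mature green, whose genotype effect correlates with that at breaker, so part of the relation is built in. In the wild-type channel alone r was -0.0565 (95% limits -0.0800 to -0.0331). There, 14.8% of the 2819 spots at least 2-fold lower in red fruit were called higher in the mutant at breaker, as were 7.93% of the 2750 at least 2-fold higher and 9.81% of all tested spots.

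The swapped arrays check the direction of the ratios. Before any dye correction each correlated positively with the mean of the forward arrays of its stage, at r = 0.841 for mature green, 0.800 for breaker and 0.567 for red. Among single arrays, the swapped red array correlated with red replicate 3 at 0.628 and with replicates 1 and 2 at 0.418 and 0.455.

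**Figure D3:**
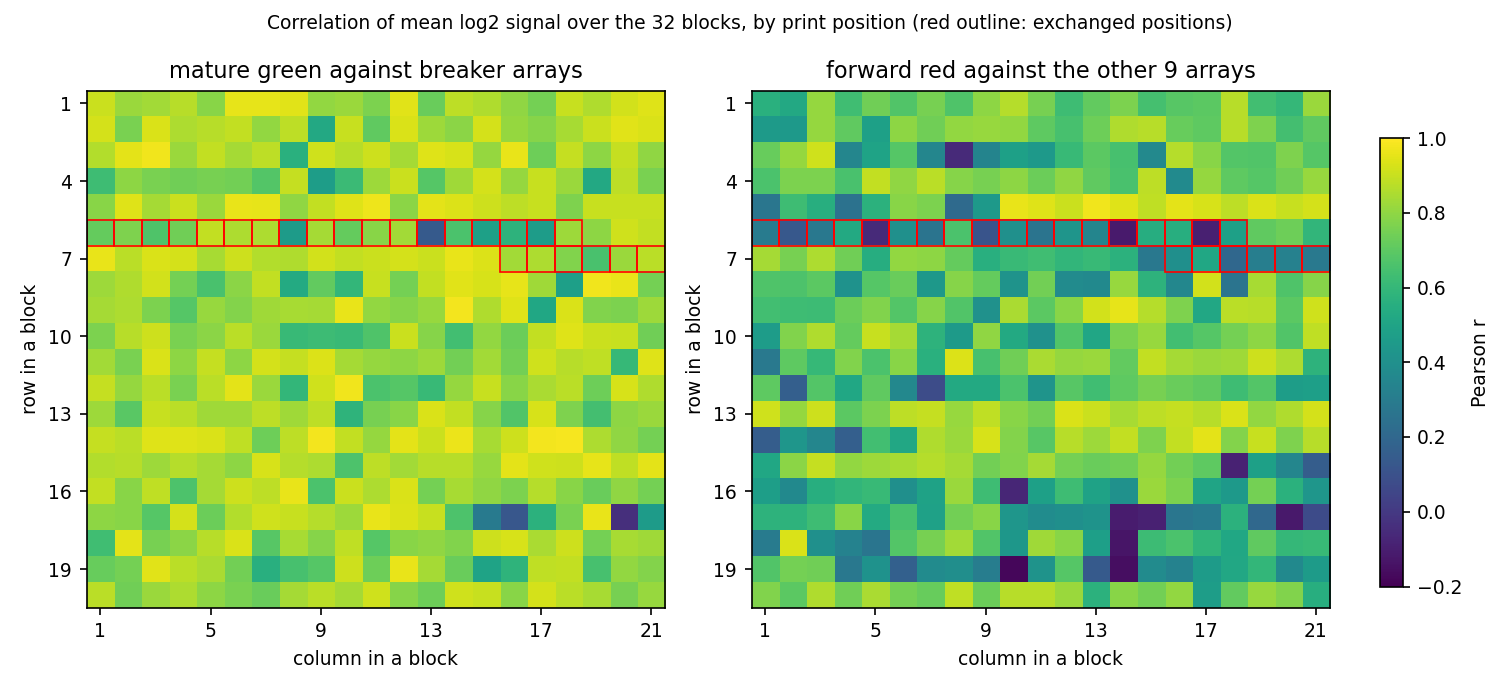
Pearson correlation of mean log2 signal over the 32 blocks of the array at each print position, by row and column in a block. The left map compares mature green with breaker arrays, the right map the forward red arrays with the other 9 arrays, and outlines mark the 24 exchanged positions.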

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

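The tests on large increases, on the print layout and on the swapped red array were chosen after related values had been seen; the tests on regrouped arrays, on replicate spread and on the spots at least 8-fold higher were written before their results.

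The genotype effect differed between stages at 1872 spots (1700 without the exchanged print positions), with 258 for breaker against mature green, 2012 for red against mature green and 1098 for red against breaker. Of 100 assignments of the 9 forward arrays to 3 stages, only the real 1 gave as many calls by the F test, and the highest of the others gave 842. The real assignment also keeps the forward red arrays, with their own print layout, together. The excess therefore cannot be credited to fruit stage alone. Spot 8167 differed between stages with an adjusted p of 0.00091 (limma). For the average over stages, 1 of 100 sign patterns, the real one, gave as many calls as the 3715 observed, and the highest other gave 1910. Within a stage only 4 sign patterns exist, too few for a share under 0.05. The real calls were 2522, 1773 and 2505, and the highest other patterns gave 0, 4 and 7. For the ripening change, 10 splits exist, again too few, with 7041 calls in the real split and 0 in the highest other. The real split also parts the print layouts, so those 7041 calls cannot be credited to ripening alone.

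Of 27 sets of 4 arrays examined for an array far from the rest, 3 had one, where chance gives about 1 in 20 for 4 like arrays. Each set here includes a swapped array and the sets share arrays, so that rate is only a rough guide. Median mutant intensity was higher on the swapped red array, where the mutant was in Cy3, than on the other red arrays, where it was in Cy5. The gap was 0.842 of the range. The mean signal correlation of the swapped red array with its stage was 0.637 against 0.848 to 0.855 for the others, a gap of 0.971. Spot 8167 at mature green was lowest on replicate 3, at -1.61, with a gap of 0.878.

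Large differences at mature green and breaker lay far more often on the higher side. Over all settings and both stages, the lowest share of increases among calls of at least 2-fold was 74.6%, with the deposited value table, so the settings tried argue against normalization, background or filter as the whole cause. On the swapped arrays alone, without dye correction, the share was 84.9% at mature green and 72.6% at breaker, where a dye bias would have turned it below 50. The genotype remains as a hypothesis, found and tested on the same data. The split over all calls was 70.8% higher at mature green and 49.6% with the deposited value table; the cause was not tested.

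The forward red arrays stand apart in signal, correlating at 0.508 to 0.643 with the other 9 arrays and at 0.952 or more among themselves. At 24 print positions the products appear exchanged: over these, the log2 ratios of red replicate 3 and the swapped red array correlated at 0.00879 in place and at 0.591 once put back. Outside these positions the signal correlation of the pair stayed at 0.667, against 0.951 for the mature green pair, so the exchange does not account for the rest of the array. Given the breaker arrays, the log2 ratios of the swapped red array kept a partial correlation of 0.526 with red replicate 3, where single breaker arrays gave at most 0.170. The values were 0.364 against 0.152 with replicate 2 and 0.258 against 0.200 with replicate 1. Replicates 2 and 3 were scanned on the same day as the swapped red array, and replicate 1 on another. The headers name replicate 3 as the partner of the swapped red array. A shared scan day alone gives no reason for replicate 3, at 0.526, to stand above replicate 2, at 0.364. The test rests on 1 swapped array and cannot fully part red RNA from the scan day. Breaker RNA alone on that array is therefore not ruled out. In a joint regression the coefficient of the swapped red array was 0.512 on the breaker arrays and 0.317 on red replicates 1 and 2. Its signal correlated with the breaker arrays at 0.880 to 0.898. It appears to share its print layout with the breaker arrays and not with the forward red arrays. Both comparisons can therefore lean toward breaker. By its label the swapped red array is of the same stage as the forward red arrays. A difference between fruit stages alone would therefore not set them apart from it, which rests on 1 array. A stage difference from the mature green and breaker arrays, and what else differs on the forward red arrays, stay open as untested.

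Effects at red resembled those at mature green less than those at breaker did. At print positions with matched signal the correlations with mature green were 0.697 for breaker and 0.370 for red, a difference of 0.327 (95% limits 0.290 to 0.359), and after division by the replicate reliabilities the difference was 0.402, so neither the layout nor a larger spread at red accounts for all of it, though a print run shared by the forward red arrays can raise their reliability. For the 139 spots at least 8-fold higher at mature green, the median on the swapped red array was 1.27 (95% limits 1.08 to 1.47), under the bound of 1.5 set beforehand for a layout cause. That median rests on 1 array and also lies above the 0.41 of the forward red arrays, so for these spots layout and stage cannot be told apart. In single arrays of one layout, the swapped breaker array correlated with the mature green arrays at 0.579 and the swapped red array at 0.452, a difference of 0.127 (95% limits 0.104 to 0.149), against 0.566 and 0.291 for the forward arrays, so part of the difference may come from the forward red arrays themselves, and a difference between fruit stages stays open as untested.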

How the results depend on the processing

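The settings on print layout, on the header-named partner of a swapped array, on widened errors on breaker against mature green signal and on the wild-type channel alone were chosen after seeing the data. Leaving out single arrays gave 1511 to 2896 calls at mature green, 979 to 2261 at breaker, 1343 to 3114 at red and 991 to 2154 for the difference between stages. Array weights gave 4199 at mature green, 1159 at breaker and 2810 for the difference between stages; the cause was not tested. Breaker fitted on its own 3 arrays gave 381. The scan day as a random block, with an estimated correlation of -0.350, gave 2939 at breaker and 3734 for the difference between stages; the cause was not tested. At print positions with matched signal alone, where fewer spots were tested, the counts were 1220, 846 and 1272 for the stages in order, 1890 for the average and 774 for the difference between stages. The ripening change gave 2368 calls from breaker minus mature green. The agreement of the swapped array fell to r = 0.735 at mature green and 0.669 at breaker with subtracted background, and at breaker to 0.647 without background correction and 0.715 with the deposited value table; the cause was not tested. The other totals of calls for each stage, the average, the difference between stages and the ripening change stayed within 1.5 times those reported, while some of their higher and lower parts moved more. Of the values of the 4 named spots under these settings, 516 kept their direction and side of the threshold, 12 kept their direction but lost the call, and 0 reversed. The lost calls were of spot 12736 at mature green and breaker (among them those with subtracted background, at 2.05 and 2.80, and with the deposited value table, at 1.60 and 2.40), spot 4225 at red (among them 1.29 with dim values set to missing) and spot 9806 at breaker. Other settings for gene lists were not run, since the files do not pair spots with genes. No paired analysis was possible because replicate numbers, given in accession order, link no arrays across stages; mutant and wild type are already compared within each array. At mature green 7.49% of the 3206 spots of lowest mean signal were called and 30.2% of the 3207 of highest.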

Other observations

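The tests on the change from mature green to breaker and on the wild-type channel were chosen after related values had been seen. Among the 1872 spots whose effect differed between stages, the most frequent course was higher in the mutant at mature green and breaker and not called at red, at 349 spots. Next came spots called at red alone, 326 higher and 289 lower, and spots called at mature green alone, 212 higher and 154 lower. At 72 spots the mutant was lower at mature green and higher at red with no call at breaker, and at 38 spots the opposite, again with no call at breaker.

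Of the 1032 spots at least 2-fold higher at mature green, 95.6% were above 0 at breaker and 81.7% at red. Of the 108 at least 2-fold lower, 70.4% were below 0 at breaker and 66.7% at red. The 538 spots at least 2-fold higher at red had a median log2 ratio of 1.14 at mature green and 0.99 at breaker. The 284 spots at least 2-fold lower at red had a median log2 ratio of -0.05 at mature green and -0.21 at breaker.

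The change in signal from mature green to breaker correlated with the genotype effect at red at -0.0674, and at -0.0778 in the wild-type channel alone. Of the 1008 spots at least 2-fold lower at breaker than at mature green, 10.8% were called higher in the mutant at red, against 11.3% of all tested spots. In the wild-type channel alone the share was 11.98% of 1027 spots. Of the 880 spots at least 2-fold higher at breaker, 9.2% were called higher in the mutant at red and 16.4% lower. Called lower at red were 8.0% of the 1008 spots and 8.2% of all tested spots.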
